A study of Homo sapiens with 51 samples.

How the data were processed

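Total RNA from 51 human breast cancer cell lines was labelled with biotin and hybridised to Affymetrix expression arrays with 54675 probe sets, 1 array per line, per the labels' protocols. The lines were untreated. The deposited values are MAS5 signal intensities on a linear scale, as the submitters' processing notes name MAS5. The version of MAS5, its settings and any detection calls are not given in the sources used here. On each deposited array the mean intensity between the 2nd and 98th percentile lay between 499.93 and 499.95, so the arrays already shared 1 scale, and this scaling was kept. Such scaling removes differences in total brightness, so only changes relative to the rest of an array can be seen. No slide or scan batch is given in the sources used here, and none could be tested.

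Groups came from the 2 labels of each line, gene expression subtype (Basal or Luminal) and Her2 status (Her2 amplified or Nonamplified). Within a group, replicate numbers follow the order of deposit and pair nothing. The name of the subtype label says that it was made from gene expression. Nothing in the labels says more about how the cultures were grown apart, and a p-value here measures the spread between lines.

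Gene names came from a table of platform annotation, in which 41097 probe sets have 1 gene symbol, 1801 have several and 11777 have none or are unlisted. The array has 62 control probe sets, which were left out of the tests, and those of GAPDH and ACTB gave the ratios of RNA quality. Only probe sets with 1 symbol were used. Of these, 41037 matched a RefSeq gene by Entrez identifier, and no symbol had to be updated. RefSeq served only for names and for the order of neighbouring genes, since no genome build is named for the arrays. Each of 19775 genes was represented by the probe set with the highest mean over all 51 arrays, chosen without regard to group. Genes above the median of their array in at least 12 arrays were tested, which left 14180. Signals were transformed as log2(signal + 16). The pseudocount of 16 shrinks the differences of dim genes. Where probe sets of a named gene differed in sign, the other probe set had an unadjusted p of 0.05 or more, except for RARA.

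The tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05, and the number of genes with at least a 2-fold difference is given beside it. 1 fit over all 51 arrays held additive terms for subtype and Her2 status, and the contrasts were Basal minus Luminal and Her2 amplified minus Nonamplified. A second fit over the 4 groups held the interaction. Of the 17 amplified lines, 15 are Luminal, so the Her2 contrast rests mostly on Luminal lines. In simulated data with 200 changed genes among 14180, the Basal against Luminal test recovered 28.4%, 64.2% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 7 false calls among 131. The Her2 test recovered 20.9%, 62.7% and 92.4%, with 8 false calls among 125. The simulated noise was normal and independent between genes, and many more genes changed than were called in the real Her2 fit. The threshold is stricter when few genes are called, so the Her2 shares do not give the power of the real fit. There ESR1 differed 4.09-fold and was not called.

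In total 22 gene lists with 277 different genes were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives except the 2 given below. They cover luminal lineage, basal epithelial, mesenchymal and epithelial junction genes, estrogen response, apocrine and androgen response, the ERBB2 amplicon and its flank, ERBB receptors and ligands, MAPK output, the PI3K pathway, proliferation, interferon response, inflammation, hypoxia and glycolysis, lipid synthesis, and markers of melanocytes, blood cells, fibroblasts, endothelium, smooth muscle and neuroendocrine cells. Some genes stand in 2 lists, such as RARA and IGFBP4 in the estrogen response and flank lists. Lists were tested with limma's camera, with a preset correlation of 0.01 and again with the estimated correlation, with Benjamini-Hochberg adjustment over the lists. List members without a probe set of their own in the annotation, among them PTEN, AR, KRT17 and TP63, were not analysed here. A list mean per line is the mean of its tested members, and for markers of other cell types the mean of all members on the array.

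The named genes are the 10 with the largest difference in each direction per main comparison, up to 2 called members per direction of each list, a fixed set of genes (ERBB2, GRB7, ESR1, PGR, AR, EGFR, GATA3, FOXA1, KRT5, VIM, CDH1, PTEN, INPP4B and MKI67), the 5 interaction genes with the smallest p, and the line with the highest mean of each list of other cell types. Further list members, genes near ERBB2 and single lines were chosen after their values were seen. Relations between measures across lines used Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples in SciPy 1.17.1, adjusted over 6 relations, and r was recomputed without the 2 lines farthest from the median of the x measure. Lines in separate clusters, with a gap over 0.35 of the range and at least 3 lines on each side, would have been tested apart, and none were found. The median signal and the 3' to 5' ratios of the GAPDH and ACTB control probe sets were compared between groups in the same way.

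Alternatives were pseudocounts of 1 and 64, quantile normalization, centring on the array median, no filter, a filter at 25 arrays, a probe set chosen by name suffix, an intensity trend with a robust prior, array weights, models without the other label, and 1 stratum of the other label alone. Lines were left out as well: AU565 and KPL1, recorded in the field as sister lines of SKBR3 and MCF7; 5 lines whose labels or origin differ from common records (MDA-MB-134VI, MDA-MB-435s, CAL-148, JIMT-1 and MFM-223); and each of the 2 Basal Her2 amplified lines in turn, HCC1954 (replicate 1) and HCC1569 (replicate 2). 2 alternatives were added after seeing the data, leaving out KPL4 and adding the log2 ACTB ratio as a covariate. Figures were drawn with matplotlib 3.10.9.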

Results

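Messenger RNA was profiled in 51 established human breast cancer cell lines, untreated and grown in medium with fetal bovine serum, with 1 array per line. The labels call 24 lines Basal and 27 Luminal, and 17 Her2 amplified and 34 Nonamplified. Together they make 4 groups, with 22 Basal Nonamplified, 2 Basal Her2 amplified, 12 Luminal Nonamplified and 15 Luminal Her2 amplified lines. The 2 subtypes are named after the outer (basal) and inner (luminal) cell layers of the breast duct, and Her2 amplification means extra copies of ERBB2, which encodes a receptor tyrosine kinase. The median signal per array lay between 88.6 and 148.9 units, and the number of lines sets the precision of every comparison. Each line is 1 sample of its group, so the spread within a group is the spread between different lines, with any technical variation included. AU565 and KPL1, recorded as sister lines of SKBR3 and MCF7 in the same groups, were counted as lines of their own. Values are log2(signal + 16), so differences of dim genes are understated.

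ERBB2 was highest in the lines labelled Her2 amplified, with a mean of 14.13 ± 1.35 (SD, n = 17) against 10.55 ± 1.06 (SD, n = 34) in the Nonamplified lines. In the model with a term for subtype the difference was 3.15 ± 0.38 (SE) on the log2 scale, an 8.88-fold difference with an adjusted p of 1.57e-07. Other ERBB2 probe sets, not used in the main analysis, differed by 3.96 and 3.18. ERBB2 lay more than 2 SD above the Nonamplified mean in 16 of the 17 amplified lines. The exception was MFM-223, at 9.64, and the next lowest was JIMT-1, at 12.70. The highest Nonamplified line, MDA-MB-175VII, reached 12.74, so the groups overlapped at JIMT-1 as well. ESR1, the estrogen receptor alpha gene, was set beside the subtype label, which is no independent check, since that label was by its name made from gene expression. It averaged 10.24 ± 2.23 (SD, n = 27) in Luminal and 7.70 ± 1.64 (SD, n = 24) in Basal lines. Its modelled difference, Basal minus Luminal, was -3.50 ± 0.57 (SE), with an adjusted p of 1.59e-05. MDA-MB-134VI, labelled Basal, had an ESR1 level of 13.03, against 9.59 in the next Basal line, BT20. EVSA-T, labelled Luminal Nonamplified, had 6.85, against 10.34 in the next lowest line of its group, MDA-MB-175VII.

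**Figure D1:**
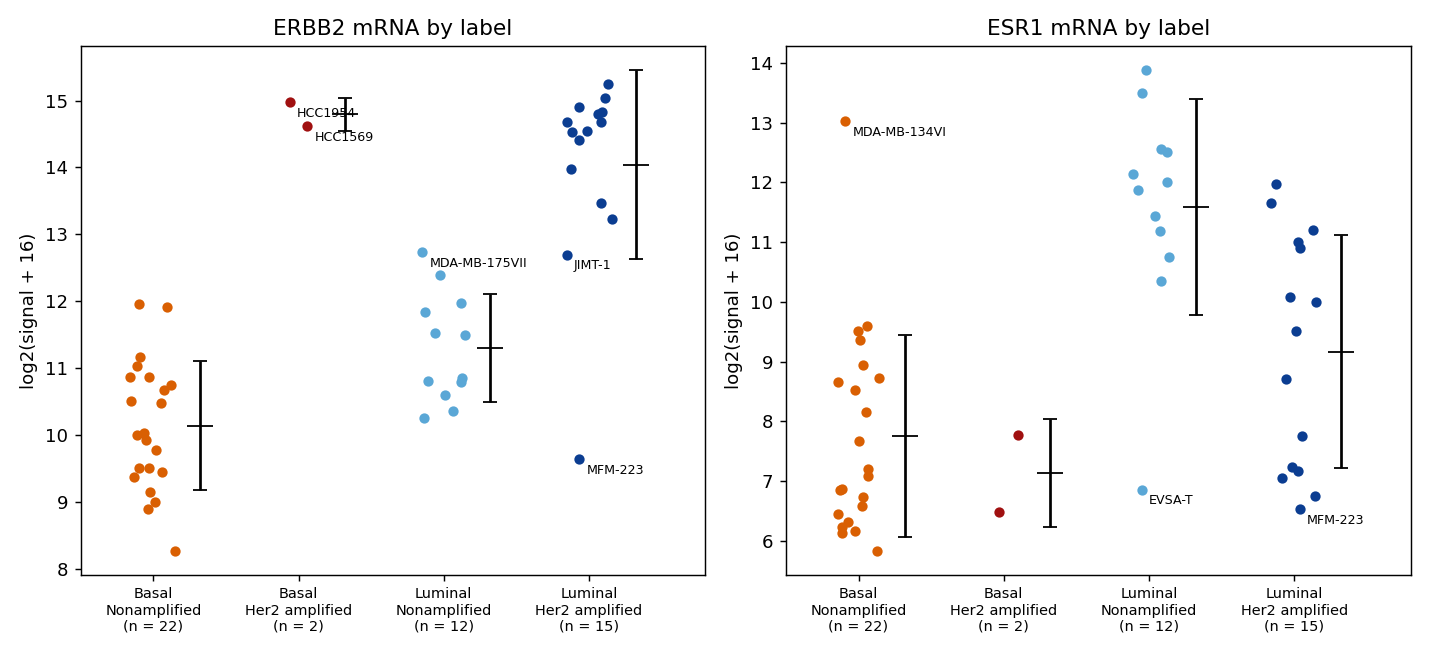
ERBB2 (left) and ESR1 (right) as log2(signal + 16), 1 point per line, in the 4 groups formed by the labels; bars show mean and SD of each group. MFM-223, at 9.64, lies below the other Her2 amplified lines for ERBB2, and MDA-MB-134VI, at 13.03, lies above the other Basal lines for ESR1.

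The first comparison asked which genes separate Basal from Luminal lines at a given Her2 status. The largest difference higher in Basal lines was in MSN. This gene, which encodes moesin, a linker of actin to the plasma membrane, was higher by 5.32 ± 0.75 (SE), a 40.0-fold difference (12.09 ± 2.52, SD, in Basal and 6.82 ± 2.24, SD, in Luminal lines). It was followed by the transcription factor ETS1 (4.98), the collagen-modifying enzyme P3H2 (4.96), the intermediate filament gene VIM (4.75) and the caveolar coat gene CAV1 (4.63). ANXA1 (4.52), CALD1 (4.33), IGFBP3 (4.29), SNAI2 (4.28) and TPM2 (4.02) completed the 10 largest. The largest differences in the other direction were ELAPOR1 at -5.19 ± 0.57 (SE), a 36.5-fold difference, then TFF1 (-5.14), the estrogen-regulated gene GREB1 (-5.05), TFF3 (-4.62) and AGR2 (-4.51). DEGS2 (-4.29), ADIRF (-4.23), AGR3 (-4.05), the luminal keratin gene KRT19 (-3.95) and the tight junction gene CLDN3 (-3.93) were the other members of that set. In limma, 2733 of 14180 genes passed an adjusted p of 0.05, of which 1284 were higher and 1449 lower in Basal lines. Of these, 1293 differed at least 2-fold, 692 higher and 601 lower. By its name the subtype label was made from gene expression, so these p-values are not independent evidence for the 2 classes. Centring each array on its median moved the median of all genes to -0.11, and 30.9% of the 3023 genes then called were higher in Basal lines, against 46.98% in the deposited scaling.

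All 14 genes of the luminal lineage list were lower in Basal lines, with a median of -3.07. FOXA1, a pioneer factor for the estrogen receptor, differed by -3.93 ± 0.53 (SE, adjusted p = 7.09e-07), GATA3 by -2.64 ± 0.59 (SE, adjusted p = 0.0012), and the keratin gene KRT8 by -1.63. The count adjusted over the list alone was also 14, and the list passed limma's camera test with a preset correlation (adjusted p = 1.71e-17) and an estimated one (adjusted p = 0.0039). Of the 13 estrogen response genes, 6 were lower in Basal lines and 9 were when adjusted over the list alone, with a median of -1.44. These included PGR, the progesterone receptor gene, at -3.60 ± 0.68 (SE), CA12 at -3.69 and PDZK1 at -2.64, and the list's test held with an estimated correlation (adjusted p = 0.024). RARA, also in this list, differed by -1.34, and 3 other probe sets differed by -0.94, -1.07 and -1.28. Another, above the array median in 2 of 51 arrays, differed by 0.84 in the opposite direction with an unadjusted p below 0.05. Of the 8 measured apocrine and androgen response genes, 2 were lower, PIP (-2.67) and ABCC11 (-0.59), and 3 when adjusted over the list alone. That list passed with the preset correlation (adjusted p = 0.0041) and not with the estimated one (adjusted p = 0.074). The ABCC11 call ended in 4 alternatives, with differences of -0.55 to -0.59, while a second ABCC11 probe set, not used in the main analysis, differed by -3.37 ± 0.59 (SE, unadjusted p = 6.44e-07).

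Of the 16 mesenchymal genes tested, 14 were higher in Basal lines and none lower, and 15 were higher when adjusted over the list alone. Besides MSN, VIM, CAV1 and SNAI2 they included TGFBI (3.90), CD44 (3.23) and the receptor tyrosine kinase gene AXL (2.82), while TWIST1 differed by 0.41 ± 0.67 (SE, adjusted p = 0.72) and SPARC by 2.23 ± 0.97 (SE, adjusted p = 0.098). The list's median was 3.37 and its adjusted p was 0.024 with an estimated correlation. Of the 10 basal epithelial genes tested, 7 were higher, with KRT5 at 3.41 ± 0.84 (SE), KRT14 at 3.17 and S100A2 at 3.59, and CDH3 at 0.12 ± 0.98 (SE) was not called. The same number passed when adjusted over the list alone, and the list's test gave 2.72e-05 with the preset correlation and an adjusted p of 0.095 with an estimated correlation. Of the 16 epithelial junction genes, 10 were lower in Basal lines, among them RAB25 (-2.99), CLDN7 (-2.21) and SPINT1 (-2.11), and 16 were lower when adjusted over the list alone. CDH1, which encodes E-cadherin, differed by -2.30 ± 0.87 (SE) with an adjusted p of 0.055, and passed the threshold in 7 alternative settings. The junction list's adjusted p was 4.68e-08 with the preset correlation and the adjusted p was 0.13 with an estimated correlation. Of the 3 smooth muscle genes tested, TAGLN (2.66) and MYLK (2.39) were higher in Basal lines, 3 passed when adjusted over the list alone, and the list's adjusted p was 0.0049, or an adjusted p of 0.10 with an estimated correlation. The TAGLN difference was 0.06, and not called, when its probe set was chosen by name suffix, and in Nonamplified lines only neither TAGLN (2.21, adjusted p = 0.054) nor the list (adjusted p = 0.071) passed.

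**Figure D2:**
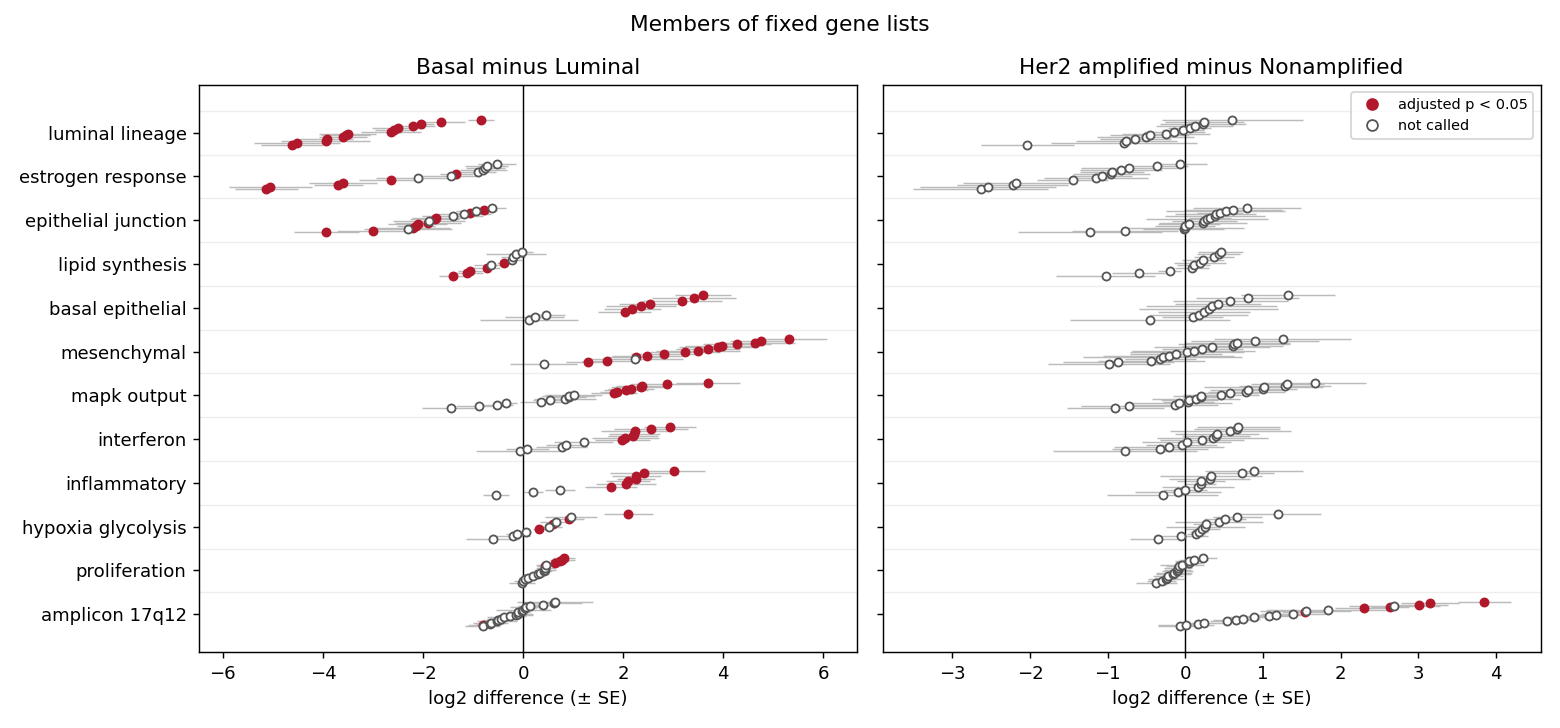
Log2 difference and SE of each tested member of 12 fixed gene lists, for Basal minus Luminal (left) and Her2 amplified minus Nonamplified (right); filled points have an adjusted p below 0.05. On the left all 14 luminal lineage genes lie below 0 and 14 of 16 mesenchymal genes are called above 0; on the right 6 genes of the ERBB2 amplicon list are called.

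Genes of signalling and immune response lists also differed between the subtypes. EGFR, the epidermal growth factor receptor gene, was higher in Basal lines by 2.93 ± 0.52 (SE), and its ligand gene HBEGF by 1.90, whereas the receptor genes ERBB3 (-2.51) and ERBB4 (-1.29) were lower, ERBB4 not without the Her2 term (-0.79, adjusted p = 0.092). The list of ERBB receptors and ligands therefore had 2 of 10 members higher and 2 lower, also when adjusted over the list alone, and an adjusted p of 0.79. Of 18 genes that follow MAPK activity, 8 were higher, including FOSL1 (3.70), EMP1 (2.87) and SPRY2 (2.38); adjusted over the list alone, 9 were higher and 1 lower. The list's adjusted p was 0.00015 with the preset correlation, and an adjusted p of 0.13 with an estimated correlation. Of 12 interferon response genes 7 were higher, among them IFIT3 (2.93), IFI27 (2.56) and IFIT1 (2.23), with the same 7 counted over the list alone. Of 10 inflammatory genes 7 were higher, among them CXCL8 (3.01), CXCL1 (2.42) and IL6 (2.09); adjusted over the list alone, 8 were higher and 1 lower. Their adjusted p-values were 2.88e-05 and 2.20e-05, and with an estimated correlation the adjusted p was 0.13 for the interferon list and 0.095 for the inflammatory list. In Nonamplified lines only IFI27 was not called (2.05, adjusted p = 0.10).

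Some metabolic and growth genes differed between the subtypes as well. FASN, which encodes fatty acid synthase, differed by -1.41 ± 0.28 (SE), SREBF1 by -1.12 and SCD by -1.05, and 5 of 10 lipid synthesis genes were lower in Basal lines, also over the list alone; the list's adjusted p was 0.0033, and the adjusted p was 0.10 with an estimated correlation. Of 11 hypoxia and glycolysis genes 4 were higher, ADM (2.10), PDK1 (0.93), ENO1 (0.59) and LDHA (0.32), and 4 over the list alone. Of 16 proliferation genes 5 were higher, with TYMS at 0.82 ± 0.22 (SE) and AURKB at 0.79, and 8 over the list alone. MKI67 was not called (0.44 ± 0.21, SE, adjusted p = 0.15), but passed without the Her2 term (0.51, adjusted p = 0.034). The PDK1 and AURKB calls each ended in 3 alternatives, among them Nonamplified lines only (0.90 and 0.65), and without the Her2 term PDK1 was at 0.61. The adjusted p-values were 0.017 for the hypoxia list and 5.11e-04 for the proliferation list, and with an estimated correlation the adjusted p was 0.15 and 0.13. The hypoxia list did not pass without the Her2 term (adjusted p = 0.091) or in Nonamplified lines only (adjusted p = 0.074). In the PI3K list IRS2 (1.79) and PIK3CD (1.73) were higher and PIK3R3 (-1.22), RPS6KB1 (-1.16), AKT1 (-0.73) and PDPK1 (-0.64) were lower, which made 2 and 4 of 14 genes, unchanged over the list alone, and an adjusted p of 0.055, or an adjusted p of 0.13 with an estimated correlation. With the preset correlation that list passed in 5 alternatives, with the lowest adjusted p, 0.028, in Nonamplified lines only, where IRS2 (adjusted p = 0.065) and PIK3R3 (adjusted p = 0.060) were no longer called. INPP4B differed by -1.10 ± 0.57 (SE, adjusted p = 0.18). The lists of the ERBB2 amplicon (1 of 20 lower, TCAP at -0.80, none over the list alone) and of its flank (1 of 8 lower, RARA, also over the list alone) had adjusted p-values of 0.31 and 0.17. The TCAP call ended in 5 alternatives, with -0.44 (adjusted p = 0.12) at a pseudocount of 64.

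Markers of other cell types were included as a check of what the cultures held. COL1A2 was the 1 called gene of 4 tested fibroblast genes (1.66). In the melanocyte list SOX10 (1.32) and MITF (0.79) were higher and TYRP1 (-1.19) lower, of 4 tested. The counts over these lists alone were the same. The COL1A2 call ended in 6 alternatives, among them quantile normalization (1.55, adjusted p = 0.064), the MITF call in 5, among them without the 5 lines of doubted label (0.72, adjusted p = 0.060), and the SOX10 call in 4, among them without HCC1569 (0.92, adjusted p = 0.15). No blood, endothelial or neuroendocrine gene was called, and these 5 lists had adjusted p-values of 0.26 or more. In the neuroendocrine list camera's direction was up while the median of its 2 members was -0.44; adjusted over the list alone 1 was higher and 1 lower.

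Within the 24 Basal lines no relation between the basal epithelial and mesenchymal list means was detected (Pearson's r = 0.01, permutation p = 0.96 before and after adjustment). Spearman's rho was -0.13 (permutation p = 0.53 and adjusted p = 0.64), and r was -0.17 without HCC1806 and CAL-148. The relation was not recomputed without the lines of doubted label, of which CAL-148 and MDA-MB-134VI (7.74 and 7.23) were low in both lists. Individual lines departed from their label's usual values. JIMT-1, labelled Luminal, had the lowest luminal lineage mean of the 27 Luminal lines (9.74) and their highest basal epithelial (10.59) and mesenchymal (10.95) means, against 9.12 in UACC-893 and 8.44 in KPL4, the next highest. CAL-148, labelled Basal, had the lowest basal epithelial (6.997) and mesenchymal (6.41) means of the 24 Basal lines. MDA-MB-134VI, also labelled Basal, had their highest luminal lineage mean (12.11) and their highest estrogen response mean (10.94, against 8.96 in Hs578T). Without these 3 lines, MDA-MB-435s and MFM-223, a set of 5 named before the data were examined because their labels or origin differ from what is commonly recorded of them, 3190 genes were called between the subtypes.

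**Figure D3:**
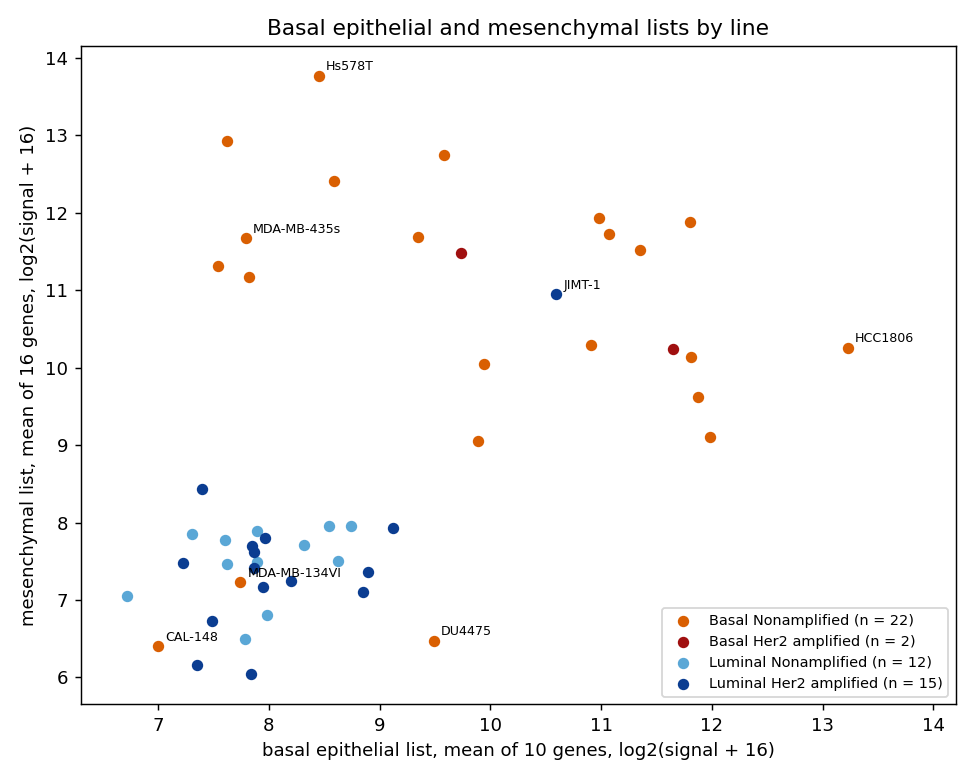
Mean of the 10 tested basal epithelial genes (x axis) and of the 16 tested mesenchymal genes (y axis), both as log2(signal + 16), 1 point per line coloured by group. JIMT-1 (10.59 and 10.95) lies among the Basal lines, and CAL-148 (6.997 and 6.41) among the Luminal lines.

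The second comparison asked which genes follow the Her2 label at a given subtype, and it returned a short list centred on ERBB2. GRB7, which encodes an adaptor protein that binds receptor tyrosine kinases, was higher in amplified lines by 3.85 ± 0.34 (SE), a 14.4-fold difference with an adjusted p of 1.34e-11. ERBB2 was higher by 3.15, STARD3 by 3.01 ± 0.37 (SE), MIEN1 by 2.64 ± 0.25 (SE), PGAP3 by 2.30 ± 0.37 (SE) and TCAP by 1.55 ± 0.31 (SE). All 6 belong to the fixed list of genes around ERBB2, and in map order they lie within 4 tested genes of ERBB2. SCUBE2, a secreted protein gene, was the 1 gene lower in amplified lines, by -2.82 ± 0.59 (SE, adjusted p = 0.033). In limma 7 of 14180 genes passed, all with at least a 2-fold difference, and 1102 had an unadjusted p under 0.05. The SCUBE2 call ended without KPL4 (-2.78, adjusted p = 0.059), without AU565 and KPL1 (-2.82, adjusted p = 0.072) and without the 5 lines named above (-2.56, adjusted p = 0.14), and also in Luminal lines only (-3.52, adjusted p = 0.14) and without the subtype term (-0.86, adjusted p = 0.56). TCAP was not called without HCC1954 (1.30, adjusted p = 0.15). Without the subtype term 161 genes were called.

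Among 20 tested genes of the amplicon list, 6 were called over all genes and 16 when adjusted over the list alone, all higher, with a median of 1.27. The list passed with the preset correlation (adjusted p = 4.88e-35) and an estimated one (adjusted p = 8.37e-06). In map order from FBXL20 to PSMD3, FBXL20 lay more than 2 SD above the Nonamplified mean in 6 amplified lines, MED1 (1.17) and CDK12 (1.08) in 9 each, NEUROD2 and PPP1R1B in 3 each, STARD3 in 15, TCAP in 8, PNMT in 4, PGAP3 in 13, ERBB2 in 16, MIEN1 in 15, GRB7 in 16, GSDMB in 9, ORMDL3 in 8 and PSMD3 in 7. Of the 34 Nonamplified lines, 3 exceeded this level for PPP1R1B, 2 for PSMD3, 1 each for FBXL20, STARD3, TCAP, PNMT, PGAP3, ERBB2 and MIEN1, and 0 for the others of these genes. The SD was each gene's own over the Nonamplified lines, so the counts are not a like measure along the map. DU4475, for example, lay 6.33 above the Nonamplified mean for PPP1R1B and 6.95 for PNMT, which widened those SDs. Between PSMD3 and TOP2A, MSL1 and WIPF2 exceeded 2 SD in 5 amplified lines each, CDC6 in 4 and GJD3 in 3. THRA, RAPGEFL1 and RARA did so in 2 each and RARA-AS1 in 0. Of the Nonamplified lines, 1 each exceeded it for MSL1, RAPGEFL1, WIPF2, RARA and GJD3. TOP2A, 14 tested genes after ERBB2, exceeded 2 SD in 0 of 17 amplified lines and differed by -0.21 ± 0.23 (SE, adjusted p = 0.86). Over the 24 tested genes from FBXL20 to TOP2A, UACC-812 had 19 above that level, UACC-893 had 17 and AU565 had 15. MDA-MB-453 had 3, HCC1569 had 4 and MFM-223 had 0. In HCC1569, ERBB2 (14.62), MIEN1 (14.67) and GRB7 (13.22) were high, and PPP1R1B lay 6.92 above its Nonamplified mean, while STARD3 (9.13) and PGAP3 (8.14), between PPP1R1B and ERBB2 in map order, stood against Nonamplified means of 8.70 and 9.33. Among Nonamplified lines DU4475 had the highest STARD3 (12.22), MIEN1 (13.21) and GRB7 (10.43).

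**Figure D4:**
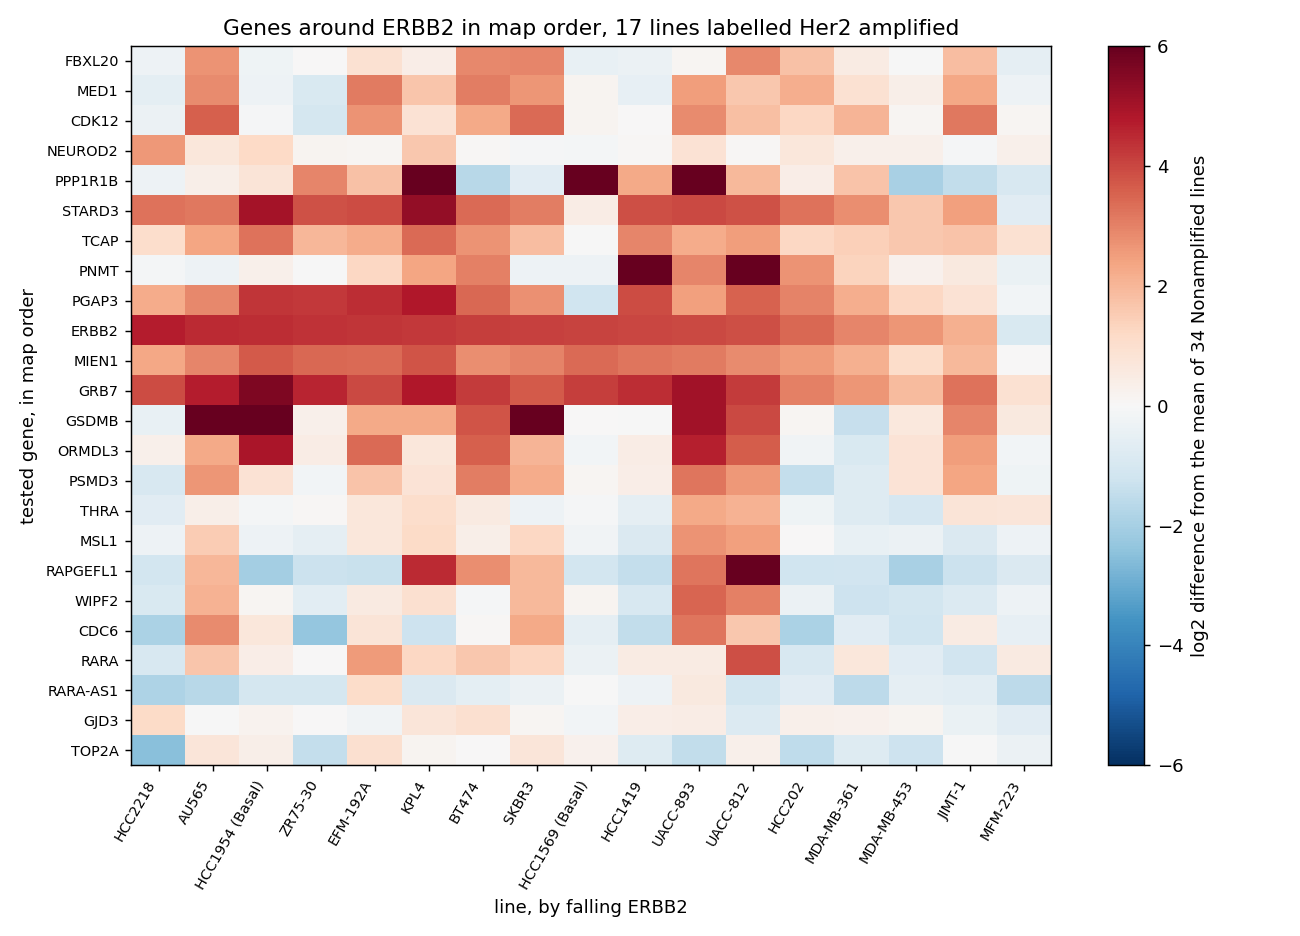
Log2 difference from the mean of the 34 Nonamplified lines for 24 tested genes in map order (rows) in the 17 lines labelled Her2 amplified (columns, by falling ERBB2); colours stop at a difference of 6 in either direction. ERBB2 and GRB7 exceeded 2 SD in 16 lines and STARD3 and MIEN1 in 15, the other genes did so in fewer, and in MFM-223 0 of the 24 genes did.

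Across the 17 amplified lines ERBB2 rose with GRB7 (Pearson's r = 0.84, permutation p = 9e-05 and adjusted p = 2.7e-04; Spearman's rho = 0.65, permutation p = 0.0055 and adjusted p = 0.016), and r was 0.82 without MFM-223 and JIMT-1, the lines farthest from the median ERBB2. The relations did not pass between ERBB2 and ORMDL3 (r = 0.32, rho = 0.25, permutation p = 0.22 for r and adjusted p = 0.43) or between ERBB2 and TOP2A (r = 0.05, rho = 0.27, permutation p = 0.86 for r and adjusted p = 0.96). Without MFM-223 and JIMT-1 these r were 0.36 and 0.23. With quantile normalization rho between ERBB2 and ORMDL3 was 0.54 (permutation p = 0.026 and adjusted p = 0.051). These tests were two-sided, with 6 relations in the family.

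The estrogen response list was lower in Her2 amplified lines at a given subtype, with a median of -1.07 over 13 genes. No member passed over all genes and 7 were lower when adjusted over the list alone, and the list passed with the preset correlation (adjusted p = 1.23e-09) and an estimated one (adjusted p = 0.011). GREB1 differed by -2.64 ± 0.87 (SE, adjusted p = 0.40), PGR by -2.22 ± 0.72 (SE, adjusted p = 0.40) and ESR1, which is no member of the list, by -2.03 ± 0.60 (SE, adjusted p = 0.34). Within the Luminal lines ESR1 averaged 9.17 ± 1.96 (SD, n = 15) in amplified and 11.59 ± 1.81 (SD, n = 12) in Nonamplified lines. Without the subtype term the list's median was -0.32 and its adjusted p was 0.40. Over the 27 Luminal lines ESR1 rose with the estrogen response list mean (Pearson's r = 0.88 and Spearman's rho = 0.90, each with a permutation p of 1e-05, the smallest these resamples can give, and an adjusted p of 6e-05), and r was 0.88 without MFM-223 and MDA-MB-453. EGFR was not related to the MAPK output list over the 24 Basal lines (r = 0.15, rho = 0.10, permutation p = 0.48 for r and adjusted p = 0.73), and r was 0.24 without DU4475 and MDA-MB-468.

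**Figure D5:**
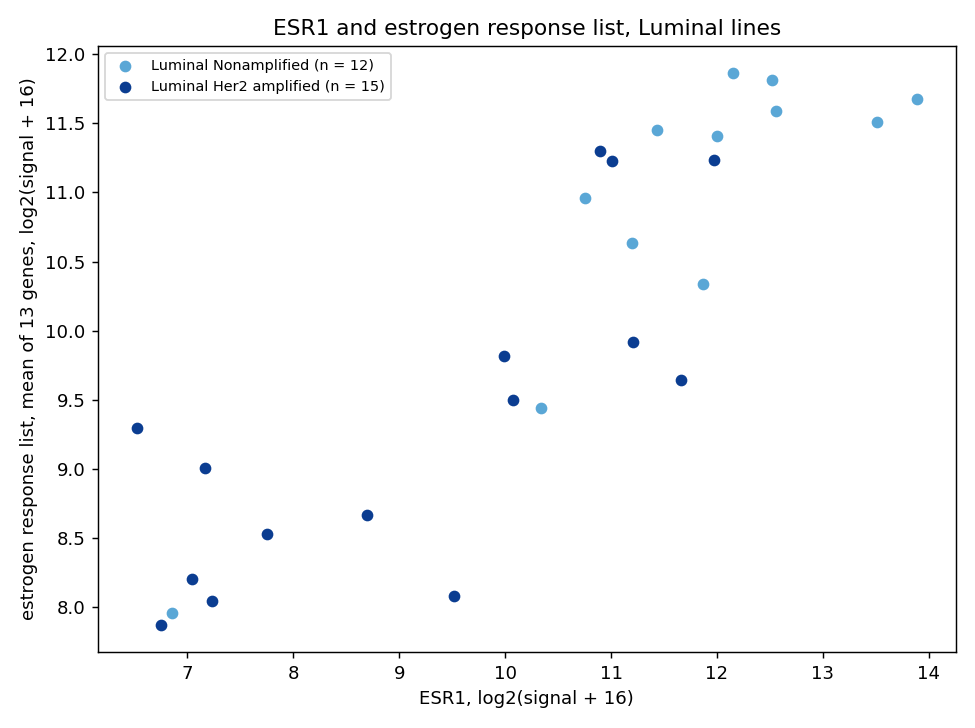
ESR1 (x axis) and the mean of the 13 estrogen response genes (y axis), both as log2(signal + 16), in the 27 Luminal lines, coloured by Her2 status. Both measures rose together (r = 0.88).

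Outside the amplicon list no list member was called over all genes, apart from ERBB2 itself, which the ERBB receptor and ligand list also holds. Adjusted over each list alone, 1 gene was lower in the luminal lineage list and 1 in the flank list. The MAPK output list (median 0.33) and the hypoxia list (median 0.26) passed with the preset correlation, each at an adjusted p of 0.032, and with an estimated correlation the adjusted p was 0.72 and 0.42. Without the 5 doubted lines neither passed (adjusted p = 0.32 and 0.063), nor did they without HCC1954 (adjusted p = 0.096 and 0.086) or without the subtype term (adjusted p = 0.78 and 0.80). The hypoxia list also did not pass without AU565 and KPL1 (adjusted p = 0.078), without HCC1569 (adjusted p = 0.22) or in Luminal lines only (adjusted p = 0.23). The other 18 lists, among them luminal lineage (median -0.20, adjusted p = 0.24), proliferation (-0.10, adjusted p = 0.24) and mesenchymal (0.06, adjusted p = 0.88), did not pass. With the preset correlation luminal lineage passed without HCC1954 (adjusted p = 0.041) and in Luminal lines only (adjusted p = 0.029), proliferation passed without the 5 doubted lines (adjusted p = 0.032), the ERBB receptor and ligand list with median centring (adjusted p = 0.040), and without the subtype term 9 lists passed. In the main fit the adjusted p with an estimated correlation was 0.76, 0.76 and 0.42 for the 3 named lists, and the alternatives were compared with the preset one only. In the flank list the median was 0.01 and the mean -0.24, with camera's direction down, and in the blood list the median was 0.09 and the mean -0.10, with camera's direction up. FOXA1 (-0.25 ± 0.56, SE), GATA3 (-0.51 ± 0.63, SE), KRT5 (0.30 ± 0.89, SE), VIM (0.61 ± 0.65, SE), CDH1 (-1.23 ± 0.92, SE), EGFR (1.11 ± 0.55, SE), INPP4B (-0.59 ± 0.60, SE) and MKI67 (-0.16 ± 0.23, SE) were not called.

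The third comparison asked whether the Her2 difference was the same in Basal and Luminal lines. In the limma interaction term 2 of 14180 genes passed, SNX19, a sorting nexin gene (-3.22 ± 0.54, SE, adjusted p = 0.0040), and EID1, which encodes an inhibitor of the EP300 acetyltransferase (-4.22 ± 0.82, SE, adjusted p = 0.032). In that term 637 of the 14180 genes had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone would give. SNX19 averaged 6.11 in the 2 Basal Her2 amplified lines against 9.66 in Basal Nonamplified lines, and EID1 8.10 against 12.18. The low EID1 mean came from HCC1569 at 4.26, since HCC1954 had 11.94, and the SNX19 values were 4.62 and 7.60. Without HCC1569, which leaves 1 line in that group, the differences were -0.38 for EID1 and -1.73 for SNX19. With a pseudocount of 64 both calls ended (adjusted p = 0.089 for EID1 and 0.087 for SNX19). The EID1 call ended as well with median centring (adjusted p = 0.078) and with a probe set chosen by suffix (adjusted p = 0.076). It also ended without the 5 doubted lines (adjusted p = 0.071) and with the ACTB ratio as a covariate (adjusted p = 0.054). CBLL2 (-1.67 ± 0.36, SE), HPGD (7.22 ± 1.60, SE) and NUDT10 (-2.15 ± 0.48, SE) followed, each with an adjusted p of 0.13.

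The array measures of RNA quality did not differ detectably between the groups. The ACTB 3' to 5' ratio averaged 1.14 ± 0.18 (SD, n = 24) in Basal and 1.31 ± 0.78 (SD, n = 27) in Luminal lines (two-sided permutation test, adjusted p = 0.59). By Her2 label it averaged 1.41 ± 0.99 (SD, n = 17) in amplified and 1.15 ± 0.16 (SD, n = 34) in Nonamplified lines (same test, adjusted p = 0.59). KPL4, a Luminal Her2 amplified line, had a ratio of 5.22, against 1.68 in BT20, the next highest. AU565 and SKBR3 gave the closest pair of arrays over all tested genes (Pearson's r = 0.95 across genes), followed by MCF7 and KPL1 (0.94), against a median of 0.79 over all pairs; genes are not independent replicates.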

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

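2 genes had a Her2 difference in Basal lines that differed from the one in Luminal lines, in the interaction term fitted over all genes. For SNX19 the Her2 difference in Basal minus that in Luminal lines was -3.22 on the log2 scale, and for EID1 it was -4.22. Only 2 lines are Basal and Her2 amplified, and SNX19 measured 4.62 in HCC1569 and 7.60 in HCC1954, while EID1 measured 4.26 and 11.94. Without HCC1569 the difference was -1.73 for SNX19 (adjusted p = 0.84) and -0.38 for EID1 (adjusted p = 1.00), so the EID1 call rests on that line. Without HCC1954, 24 genes were called, which included both, and without HCC1569, 10 genes were called, which included neither. No further explanation of these values was tested.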

How the results depend on the processing

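No paired analysis was possible because the labels carry no replicate numbers. The number of genes called between Basal and Luminal lines ranged from 2252 to 3472 over 17 alternatives, within 1.5 times 2733, and the ERBB2 difference by Her2 label, the ESR1 difference by subtype and Pearson's r of the 6 relations kept their direction and their side of the threshold under every alternative run for them. Leaving out the 2 farthest lines moved r between the basal epithelial and mesenchymal lists from 0.01 to -0.17, neither of which passed. The Her2 count of 7 stayed between 5 and 10 except without the subtype term, where 161 genes were called, 91 of them at least 2-fold, and 9 lists passed against 4. 15 of 17 amplified lines are Luminal, so that model mixes the labels. The interaction count of 2, the same with the 2-fold minimum, became 4 with a pseudocount of 1, 0 with a pseudocount of 64 or a probe set chosen by suffix, and 1 with median centring, without the 5 doubted lines or with the ACTB ratio as a covariate (a term chosen after seeing the data); it ranged from 10 to 24 when either Basal Her2 amplified line was left out, which leaves 1 line assumed to vary like the other groups. The cause was not tested. GRB7 changed sign between the subtypes without the Her2 term, to -1.77 from 0.05. Without the subtype term the Her2 medians changed sign in 5 lists that passed in the main fit or in that one. They moved to 1.26 for luminal lineage, -1.39 for mesenchymal, -0.10 for MAPK output, -0.80 for interferon and -0.68 for inflammatory genes. Lists that passed in neither fit were not counted here. Of 1395 values of single genes under alternatives, 1329 kept their side of the threshold, 50 lost the threshold and 15 gained it. For lists these were 453, 12 and 14 of 484. A change of sign was counted apart only where the main or the alternative value passed. The 1329 and the 453 therefore include values that changed sign without passing. FOXA1, for example, averaged 11.21 in amplified and 9.38 in Nonamplified lines, against a difference of -0.25 with the subtype term. Signal over background limits dim genes, for which no detection call was used.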

Other observations

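Tests of splits of the labels, of MFM-223 and of MDA-MB-435s were chosen after the result was seen; those on the estrogen response list were written before. Hs578T stood apart among the Basal lines in markers of fibroblasts. Its fibroblast list mean was 12.60, against 9.72 in HCC1395, the next highest, and a median of 6.79 over the 51 lines, and its smooth muscle list mean was also the highest, at 11.72, but by less than 1 SD (1.23), with CAL-51 at 10.90 and HCC1569 at 10.16. It also had the highest mesenchymal mean (13.77) and the lowest epithelial junction mean (5.69) of the 24 Basal lines. The Basal lines spread far more in the junction list (SD 2.11) than the Luminal lines (SD 0.29). BT483 had the highest neuroendocrine list mean (8.98, against 8.65 in UACC-812), MDA-MB-415 the highest blood list mean (7.47, against 7.42 in HCC1806) and KPL4 the highest endothelial list mean (7.59, against 7.47 in BT20). Of the genes on the array, 2 of 5 neuroendocrine, 4 of 6 blood and 2 of 5 endothelial genes passed the filter. KPL4 and BT20 had the highest ACTB ratios (5.22 and 1.68), and KPL4 the highest median signal (148.9). Background signal in these means was not told apart from expression of the markers.

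HPGD, which encodes an enzyme that inactivates prostaglandins, measured 13.30 in HCC1569 and 9.29 in HCC1954, against a mean of 6.21 ± 1.19 (SD, n = 22) in Basal Nonamplified lines. SCUBE2 was measured at 10.79 in HCC2218 and 10.94 in UACC-812, while MDA-MB-361 had 9.11 and the other 12 Luminal Her2 amplified lines had 7.61 or less. DU4475, labelled Basal Nonamplified, had STARD3 at 12.22 and MIEN1 at 13.21, more than 2 SD above the Nonamplified means, with ERBB2 at 9.38.

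Of 100 splits of the Her2 labels within each subtype, 1, the real one, gave as many as 7 genes, and the highest other split gave 2. All of the 7 but SCUBE2 belong to the fixed list of genes around ERBB2, whose amplification the label names. The real labels would therefore exceed random splits in any case, and the count says nothing of SCUBE2 alone. Of 100 splits of the subtype labels within each Her2 status, 1, the real one, gave as many as 2733 genes, and the highest other split gave 39, but that label was by its name made from gene expression and would exceed random splits in any case, so this test decides nothing.

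MFM-223, labelled Luminal Her2 amplified, had an ERBB2 level of 9.64, against 12.70 or more in the other amplified lines. Degraded RNA is argued against by its ACTB 3' to 5' ratio of 1.16, near the median of 1.13 over all arrays. Its median signal also lay within the range of the other arrays. The ratio lay within the range of the other Luminal Her2 amplified lines too, but KPL4 (5.22) set that bound, with HCC202 next at 1.41. By GRB7 alone a swap with a line labelled Nonamplified could not be decided. The highest GRB7 level of those lines was 10.43, below the lowest, 10.95, of the other amplified lines. The gap was less than the Nonamplified SD of 0.88, a margin set after the values were seen, and ERBB2, STARD3, MIEN1 and PGAP3 overlapped. The highest GRB7 and the highest ERBB2 came from different lines, however. DU4475, with the highest GRB7, had ERBB2 at -1.17 from the Nonamplified mean. MDA-MB-175VII, with the highest ERBB2 (12.74), had GRB7 at 9.81, and every Nonamplified line but DU4475 had GRB7 at 9.99 or less. These values argue against a swap with any of the 34 lines. All 5 of the genes ERBB2, GRB7, STARD3, MIEN1 and PGAP3 lay in MFM-223 within the range of the Nonamplified lines. A wrong Her2 label of this line may therefore account for its values, and an amplification without higher expression was not tested.

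The estrogen response list was lower in Her2 amplified lines, by -1.32 ± 0.34 (SE) in its mean with a term for subtype. With the ACTB ratio as a covariate the difference was -1.36 ± 0.34 (SE), which argues against RNA quality as the whole cause. With ESR1 as a covariate the difference fell to -0.49 ± 0.25 (SE), within 1 SE of 0.5 of its size, a bound set beforehand, so that lower ESR1 in the amplified lines as the main source and an effect beyond ESR1 cannot be told apart. ESR1 was itself measured on these arrays, and the order of cause between Her2 and ESR1 was not tested.

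MDA-MB-435s, labelled Basal Nonamplified, had the highest mean of the 8 melanocyte genes on the array (9.32, against 7.89 in the line MX1 and a median of 6.44). A minority of melanocytic cells in an epithelial line is argued against by its epithelial junction mean, 5.86, which ranked 2 from the bottom of the 24 Basal lines, with CDH1 at 5.46, KRT19 at 4.20 and EPCAM at 7.04, although KRT18 was at 13.13 against a Basal median of 14.08. A minority in a line that itself lacks junction genes is not excluded. A melanocytic origin of the whole line is a hypothesis that the test left open, because 3 of the 8 genes (SOX10 at 12.49, S100B at 11.95 and TYR at 9.95) were highest of all 51 lines in it, fewer than the 5 set as the bound. MITF (11.09, with 11.09 in MX1) and MLANA (7.49, against 7.52 in KPL4) lay just below the highest line, PMEL (7.23) and GPR143 (8.19) lay above their medians of 6.22 and 5.25, and TYRP1 (6.18) lay near its median of 6.07. MLANA, PMEL, GPR143 and S100B did not pass the filter. The KPL4 array had the highest ACTB ratio (5.22), so the rank of the dim gene MLANA says little.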
